A study of Mus musculus with 6 samples.

How the data were processed

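RNA from 6 samples of mouse bone marrow cells transformed by the MLL-AF9 fusion was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript cluster with a set of short probes spread along the gene. Per the labels, the cells started as c-kit+ progenitors and received either the empty retroviral vector pMIG, which carries GFP, or pMIG-TGIF1, with 3 arrays in each group. GFP-positive cells were sorted on day 3 after transduction, kept 1 day in medium and lysed, and 300 ng of total RNA per sample was amplified and biotin-labelled, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate transductions or cultures, so the p-values measure only the spread between these samples, which may be technical.

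The deposited expression values are probe set intensities on a linear scale that the authors obtained with RMA, per the submitters' processing notes, which name Partek and RMA without versions or settings. RMA corrects the background, normalizes between arrays and summarizes the probes of a set. The same intensities stood in both deposited tables, with 28853 probe sets in each and a largest difference of 0. One of these tables also holds a p-value to 2 decimals and a signed fold change of TGIF1 over empty vector, both computed by the authors with a test not given in the sources used here. For 99.9% of the named probe sets the deposited p-value equalled that of an ordinary linear model on the log2 intensities, within a tolerance of 0.0051. All 6 columns of per-sample values in each table were matched to a sample. The scanner files, the genome build behind the array annotation and the RMA settings were not used here or not given in the sources used here.

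Each probe set was named from the gene symbol and RefSeq accession in the deposited table. Its longer gene assignment text, which ends at 80 characters, was not used for names. Symbols were updated through a RefSeq gene table of mouse that was used only for names and for which genes neighbour each other. Of the 25123 probe sets with a symbol, 18873 were named through a RefSeq accession, 2487 through a current symbol and 1740 through an older symbol. The symbol in the table was kept for 2023. The update changed 4203 symbols, and 22319 distinct symbols resulted. The 3730 probe sets without a symbol were left out of the test. Each probe set carries 1 symbol here, although some may read more than 1 gene.

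Intensities were log2 transformed and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default moderation, no filter on dim probe sets), as pMIG-TGIF1 minus pMIG over all 6 arrays. A transcript cluster was called at a Benjamini-Hochberg adjusted p under 0.05. A further count required at least a 1.5-fold change. Errors given as SE are those of the moderated fit, and intervals are 95% confidence intervals. The words rose and fell are used of calls, in the arrays labelled pMIG-TGIF1 relative to the empty vector.

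The 28 gene lists, with 711 members, were fixed before the data were examined, and 704 members were matched to a probe set. They cover MLL-fusion self-renewal genes, stem and progenitor genes, primary granule, late neutrophil, and monocyte and macrophage genes. Further lists cover dendritic cell and MHC class II genes, lysosome, myeloid transcription factors, G1/S replication, G2/M mitosis, and cell cycle inhibitors with p53 targets. Others hold apoptosis, TGF-beta and SMAD, retinoid, ribosome biogenesis and MYC, interferon response, NF-kB inflammatory, immediate early, heat shock and integrated stress, cholesterol synthesis, and adhesion and homing genes. Lists of other lineages cover erythroid, megakaryocyte, mast cell and basophil, eosinophil, B cell, T and NK cell, and stroma and endothelium genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean), and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The counts adjusted over the list alone repeat the Benjamini-Hochberg step within each list.

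Genes were named by a rule fixed beforehand. It took the 10 genes higher and the 10 lower with the largest change among calls with all 3 arrays of one group above all 3 of the other, predicted genes skipped. It also took 16 genes chosen in advance, and up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here. Other members are named as examples chosen after their values were seen.

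The alternatives fixed beforehand were the replicate number as a block, an intensity trend with a robust prior, no moderation, renewed quantile normalization and centring of each array on its median. Others were leaving out the dimmest 30% or 50% of probe sets, testing all probe sets, 1 probe set per gene, array weights, the other deposited table, leaving out each array in turn, and both other list tests. Data were also simulated for the comparison of pMIG-TGIF1 with pMIG over 25123 probe sets, 200 of them changed. The fit called 38.8% of 1.5-fold, 83.6% of 2-fold and 97.0% of 4-fold changes, with 1 unchanged probe set called and 0 in the wrong direction. In the real data 24.7% of transcript clusters were called, a far larger share than was changed here, and each simulated probe set was drawn independently. These rates therefore do not give the sensitivity of the real comparison. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

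The number of arrays limits the precision. No detection calls or background signals were used here, so whether a dim probe set lay above background is unknown, and RMA compresses the fold changes of dim probe sets.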

Results

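Gene expression was measured in mouse bone marrow cells transformed by MLL-AF9, a fusion of the histone methyltransferase MLL with AF9 that drives acute myeloid leukemia. The cells had been transduced with an empty retroviral vector (pMIG, n = 3 arrays) or with the same vector carrying TGIF1 (pMIG-TGIF1, n = 3 arrays), sorted for GFP on day 3 and cultured for 1 further day. TGIF1 is a homeodomain protein known to repress TGF-beta and retinoid responsive transcription. The series title poses the question of what TGIF1 does in MLL-rearranged leukemia, and the single comparison of the design is TGIF1 vector against empty vector.

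Tgif1 itself went against the label. Its only probe set (10452633) read 320, 376 and 408 in the pMIG arrays and 239, 239 and 258 in the arrays labelled pMIG-TGIF1, a log2 fold change of -0.58 ± 0.11 (SE; 1.49-fold lower, limma adjusted p = 0.00286). All 3 arrays labelled pMIG-TGIF1 lay below all 3 pMIG arrays, and the exact two-sided permutation p was 0.1, the smallest that 20 assignments allow. The authors' deposited table gives the same probe set a fold change of -1.49 with p = 0.01. The probes may lie outside the sequence carried by the vector, or the vector may carry the TGIF1 of another species, and the probe set then checks nothing. Every direction below therefore rests on the labels alone. The related Tgif2 differed by -0.038 ± 0.11 on the log2 scale (adjusted p = 0.867).

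**Figure D1:**
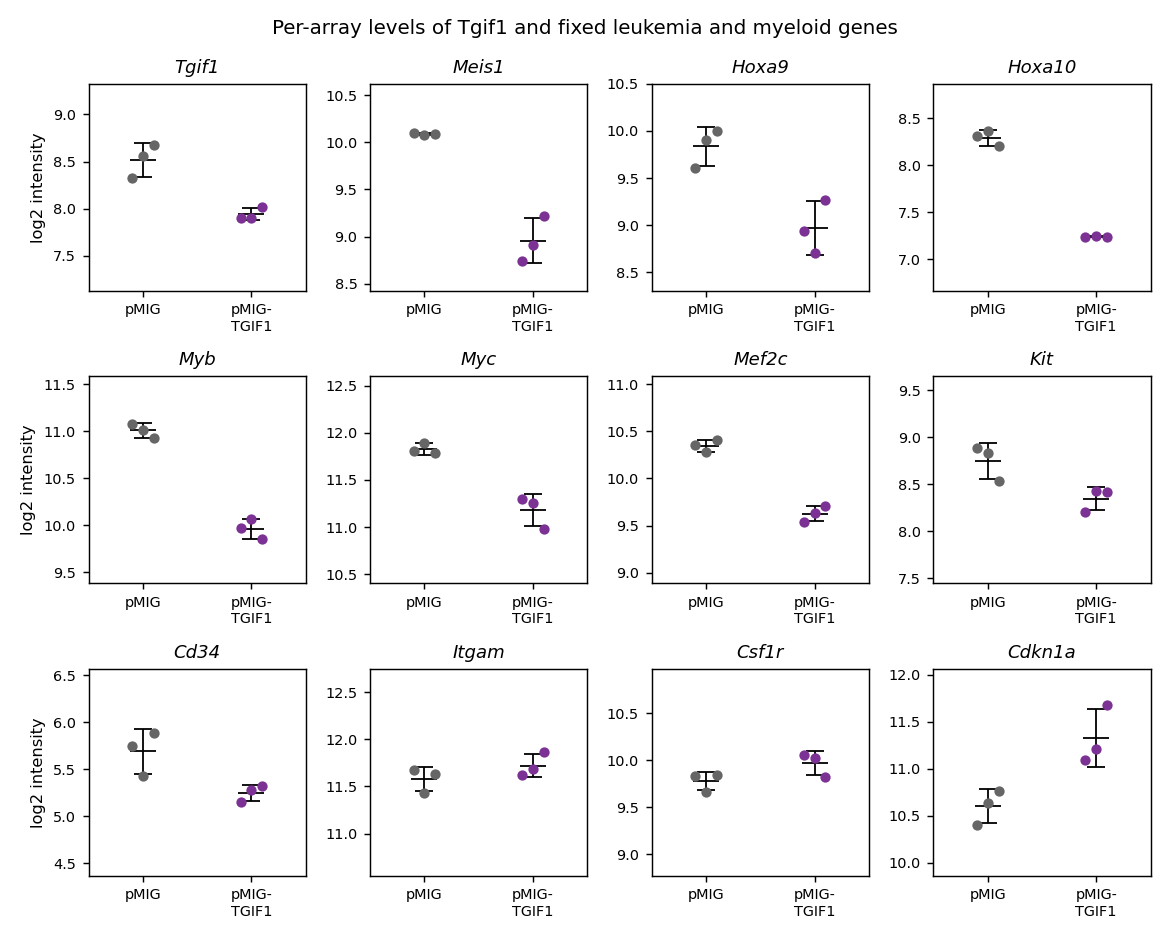
Log2 intensity (y axis) of Tgif1 and 11 further genes named in advance in each pMIG array (grey) and each array labelled pMIG-TGIF1 (purple). Points are arrays, horizontal marks are means and bars are SDs (n = 3 per group). Tgif1, Meis1, Hoxa9, Hoxa10, Myb, Myc and Mef2c lay lower in all 3 arrays labelled pMIG-TGIF1, while the groups overlapped for Itgam and Csf1r.

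In the arrays labelled pMIG-TGIF1, 18 of 28 MLL-fusion program genes, 28 of 32 DNA replication genes, 30 of 30 mitosis genes and 24 of 30 ribosome biogenesis genes fell. Of monocyte and macrophage genes 24 of 37 rose, of immediate early genes 22 of 25, of interferon genes 26 of 33 and of NF-kB inflammatory genes 16 of 25. These 8 lists were called by camera with the preset correlation and lost the call with an estimated correlation (adjusted p = 0.171 to adjusted p = 0.242). Predicted genes aside, the steepest rises were those of Ppbp and Pf4, platelet-type chemokines, Serpinb2, a plasminogen activator inhibitor, and Thbs1, the matrix protein thrombospondin 1. Ppbp was 31.4-fold higher (95% CI 21.9 to 45.0), Serpinb2 27.0-fold, Thbs1 25.7-fold and Pf4 18.2-fold. The steepest falls were smaller. Cltb, a clathrin light chain, was 6.33-fold lower (95% CI 4.92 to 8.15), and Gria3, a glutamate receptor subunit, was 4.95-fold lower. These 6 genes had adjusted p-values between 2.59e-09 (Thbs1) and 2.37e-06 (Cltb).

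Among the 10 highest rises were also the lectin receptor Clec4a1 (15.9-fold), the chemokine Ccl24 (15.8-fold), the steroid-metabolizing enzyme Akr1c18 (14.7-fold) and the small GTPase Rhoc (12.9-fold). Ptgs2, the inducible cyclooxygenase, was 12.7-fold higher, and Marcks, a protein kinase C substrate, was 12.6-fold higher. Among the 10 steepest falls were Neto2 (4.55-fold), Kbtbd8 (4.47-fold), the mast cell IgE receptor subunit Ms4a2 (4.02-fold) and D6Wsu163e (3.82-fold). The spindle and kinetochore gene Ska2 (3.82-fold), the adhesion molecule Ncam1 (3.69-fold), the ribosomal RNA processing gene Rrp12 (3.53-fold) and the early activation marker Cd69 (3.33-fold) completed them.

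In all, 6200 of 25123 transcript clusters (24.7%) were called by limma, 2892 of them higher and 3308 lower in the arrays labelled pMIG-TGIF1. At least a 1.5-fold change was seen in 3092 calls, 1511 higher and 1581 lower. Large changes were mostly rises, with 667 calls at least 2-fold higher against 400 lower, and 129 at least 4-fold higher against 7 lower. The 2 groups of arrays did not overlap in 38.4% of transcript clusters, where chance gives 10%. The first principal component, which held 75.4% of the variance, set the groups apart, and correlations across genes ran from 0.994 to 0.997 within groups and from 0.975 to 0.984 between them. Array medians were 6.33, 6.31 and 6.32 on the log2 scale in pMIG and 6.41, 6.41 and 6.45 in the arrays labelled pMIG-TGIF1. Centring each array on its median shifted the median log2 fold change of all transcript clusters by -0.11, from 0.010 to -0.10, and turned the share of calls that were higher from 46.6% into 30.9% (2179 higher, 4870 lower). The ordinary model without moderation called 3401 transcript clusters.

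**Figure D2:**
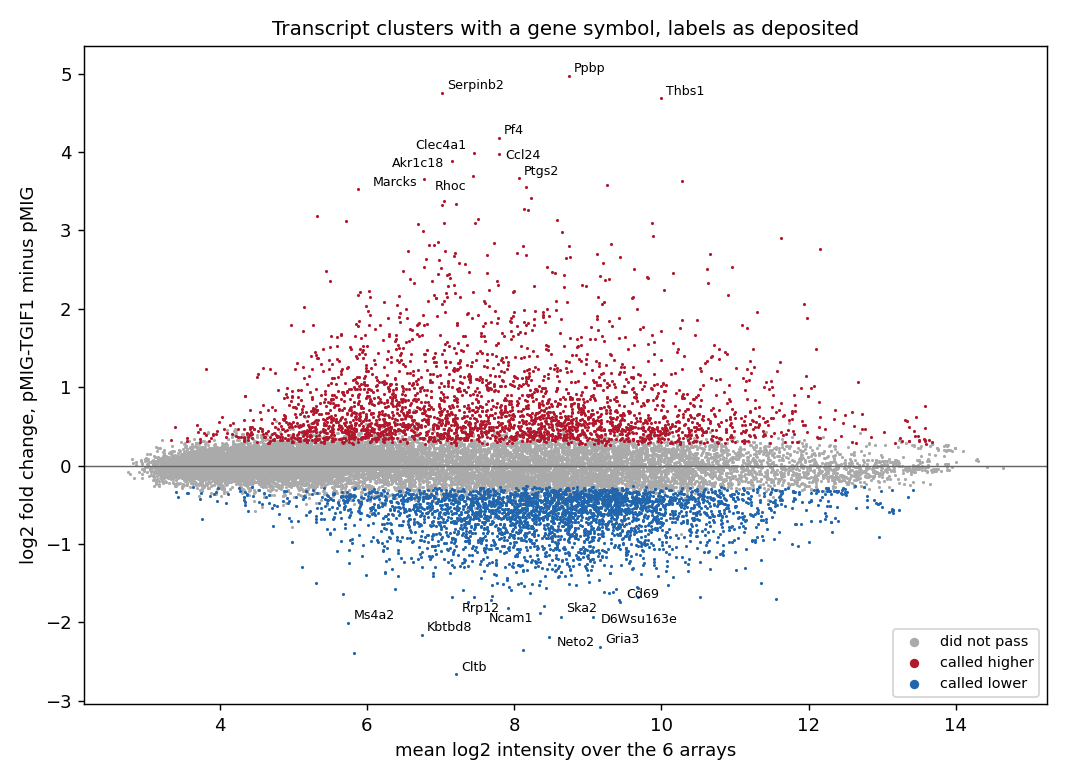
Log2 fold change between the arrays labelled pMIG-TGIF1 and the pMIG arrays (y axis) against mean log2 intensity over 6 arrays (x axis), 1 point per transcript cluster. Red and blue points passed an adjusted p of 0.05, and the 10 steepest rises and falls are named, predicted genes skipped. Rises reached 4.97 (Ppbp) and named falls -2.66 (Cltb) on the log2 scale.

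The MLL-fusion self-renewal list, the genes that MLL fusions are known to keep active in leukemic progenitors, fell. Of its 28 measured members, 18 fell and 1 (Zeb2) rose, or 23 and 1 adjusted over the list alone. The homeobox genes Hoxa6 (log2 -1.46 ± 0.10 SE), Hoxa10 (-1.05 ± 0.09) and Hoxa9 (-0.87 ± 0.15) fell, as did their cofactor Meis1 (-1.13 ± 0.12) and the sine oculis homolog Six4 (-1.24 ± 0.09). The transcription factors Myb (-1.05 ± 0.10), Mef2c (-0.72 ± 0.09) and Myc (-0.65 ± 0.11) fell as well. Pbx3, another Hox cofactor, was lower by an amount that missed the threshold (-0.48 ± 0.17, adjusted p = 0.0583). It was called without pMIG-TGIF1 replicate 3 (-0.68, adjusted p = 0.00265), with array median centring (-0.59, adjusted p = 0.0186) and with array weights (-0.54, adjusted p = 0.0201). At the same fold it was also called with the intensity trend and robust prior, with the dimmest 30% or 50% left out and with 1 probe set per gene (adjusted p = 0.0418 to adjusted p = 0.0481). The call of Hoxa9 was lost without moderation (adjusted p = 0.0716). Camera gave the list an adjusted p of 5.39e-10 at the preset correlation and adjusted p = 0.171 with an estimated correlation.

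The stem and progenitor list moved in both directions and was not called (camera adjusted p = 0.828). Of 26 measured members 3 rose and 7 fell, or 3 and 8 adjusted over the list alone, and the median was 0.040 while camera pointed down. Ly6a, which encodes the stem cell antigen Sca-1, rose 7.48-fold, whereas Etv6 (log2 -0.63 ± 0.10) and the mucin Muc13 (-0.74 ± 0.12) fell. The stem cell factor receptor Kit (-0.40 ± 0.12, adjusted p = 0.0311) and Cd34 (-0.44 ± 0.12, adjusted p = 0.0247) fell slightly. Both lay near the threshold and lost the call under several alternatives, at folds of similar size (-0.33 to -0.40 for Kit, -0.34 to -0.45 for Cd34). With all 6 arrays Kit was lost with quantile normalization (adjusted p = 0.0659), with the replicate block (0.0547) and without moderation (0.141), and Cd34 without moderation (0.139). Kit was lost without pMIG replicate 1 (adjusted p = 0.121), pMIG replicate 2 (0.108) or pMIG-TGIF1 replicate 1 (0.104). Cd34 was lost without pMIG replicate 1 (0.0860), pMIG replicate 3 (0.108), pMIG-TGIF1 replicate 1 (0.0760) or pMIG-TGIF1 replicate 2 (0.0518).

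Proliferation genes fell. All 30 measured G2/M mitosis genes fell, also when adjusted over the list alone, and 28 of 32 G1/S replication genes fell with 0 rising, or 30 and 1 adjusted over the list alone (27 and 1 with quantile normalization). The proliferation marker Mki67 (log2 -1.42 ± 0.14), the kinesin Kif23 (-1.07 ± 0.09), Ckap2l (-1.27 ± 0.11) and the kinase Nek2 (-1.28 ± 0.12) fell in the mitosis list. DNA ligase Lig1 (-1.63 ± 0.19), the ribonucleotide reductase subunit Rrm1 (-1.20 ± 0.14) and the licensing factor Cdt1 (-1.15 ± 0.14) fell in the replication list. Without pMIG-TGIF1 replicate 3, the array with the lowest limma array weight (0.56), the median log2 fold change went from -1.14 to -0.87 for replication and from -0.93 to -0.85 for mitosis, with 26 and 29 genes called lower. Camera adjusted p-values were 1.66e-20 for mitosis and 6.90e-16 for replication. With an estimated correlation the calls were lost, with adjusted p = 0.171 for mitosis and adjusted p = 0.230 for replication. The estimates were 0.49 for mitosis and 0.80 for replication, far over the preset 0.01 behind the smaller p-values.

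Of 30 ribosome biogenesis and MYC genes, 24 fell and 1 (Ldha) rose, the same counts when adjusted over the list alone (camera adjusted p = 4.68e-10, and adjusted p = 0.242 with an estimated correlation). Wdr12 (log2 -1.23 ± 0.15) and Bop1 (-1.27 ± 0.15), partners in a large subunit assembly complex, and the purine synthesis enzyme Ppat (-1.02 ± 0.14) fell together with Rrp12. Without pMIG-TGIF1 replicate 3 the median log2 fold change went from -0.86 to -0.61, with 22 genes called lower. The rise of Ldha was lost on leaving out any single array.

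Cell cycle inhibitors and p53 targets split. Of 32 measured members 10 rose and 5 fell, or 11 and 5 adjusted over the list alone. Without pMIG replicate 2 or 3 or pMIG-TGIF1 replicate 1 or 2, 3 members fell. Plk2 (log2 2.53 ± 0.19), Btg2 (1.53 ± 0.20), Trp53inp1 (1.03 ± 0.10) and Tob1 (1.00 ± 0.09) rose, and so did Cdkn1a, which encodes the inhibitor p21 (0.72 ± 0.15, adjusted p = 0.00565, lost without moderation at 0.104). The list passed camera weakly (adjusted p = 0.0329). It did not pass without pMIG replicate 1 (adjusted p = 0.0512), without pMIG-TGIF1 replicate 3 (0.0571), without moderation (0.0589) or with an estimated correlation (0.354).

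Monocyte and macrophage genes rose. Of 37 measured members, 24 rose and 1 (Cx3cr1) fell, or 27 and 1 adjusted over the list alone. The coagulation factor subunit F13a1 rose 12.3-fold, the lipopolysaccharide coreceptor Cd14 5.02-fold, the costimulatory ligand Cd86 4.28-fold and the lipopolysaccharide receptor Tlr4 2.68-fold. Itgam, which encodes CD11b (log2 0.14 ± 0.11, adjusted p = 0.419), and the M-CSF receptor Csf1r (0.19 ± 0.10, adjusted p = 0.244) did not pass. Camera gave an adjusted p of 3.33e-13, and adjusted p = 0.171 with an estimated correlation.

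Lysosome genes and myeloid transcription factors rose too. In the lysosome list 18 of 30 rose and 1 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 1.68e-07, adjusted p = 0.191 with an estimated correlation). The protease genes Ctsl (5.80-fold), Lgmn (3.15-fold) and Ctss (2.10-fold) and the glycoprotein gene Gpnmb (4.51-fold) led it. Among myeloid transcription factors 15 of 27 rose and 3 fell, or 17 and 3 adjusted over the list alone (camera adjusted p = 2.68e-06, adjusted p = 0.171 with an estimated correlation). Nr4a1 rose 9.61-fold, Id2 4.95-fold, Egr2 3.95-fold and Maf 3.67-fold. Cebpa, a regulator of granulocyte formation, did not pass (log2 0.32 ± 0.17, adjusted p = 0.238). Of the 27 factors 16 also stand in at least 1 other list, Nr4a1, Id2, Egr2 and Maf among them.

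Granule genes did not move as one group. Among primary granule genes 2 of 13 rose and 5 fell, or 2 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.126). The protease Ctsc rose 2.37-fold, while Ms4a3 fell 3.25-fold, the repressor Gfi1 2.15-fold and the protease inhibitor Serpinb1a 2.14-fold. Among late neutrophil genes 12 of 29 rose and 2 fell, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00257, adjusted p = 0.193 with an estimated correlation). The gelatinase Mmp9 (3.12-fold), the neutrophil antigen Ly6g (2.68-fold) and the stefin Stfa3 (2.48-fold) rose, and the granule protein Ngp fell 1.97-fold.

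Inducible genes rose in several lists. Of 25 immediate early genes 22 rose and 2 fell, the same counts when adjusted over the list alone (camera adjusted p = 9.28e-13, adjusted p = 0.193 with an estimated correlation). Besides Nr4a1 and Egr2, Atf3 (3.77-fold) and Klf6 (2.89-fold) rose. Of 25 NF-kB inflammatory genes 16 rose and 3 fell, again the same when adjusted over the list alone (camera adjusted p = 2.13e-07, adjusted p = 0.171 with an estimated correlation). Il6 rose 9.11-fold, the monocyte chemokine Ccl2 7.60-fold and the cytokine Il1a 5.10-fold, next to Ptgs2. Of 33 interferon response genes 26 rose and 2 fell, or 27 and 2 adjusted over the list alone (camera adjusted p = 2.60e-13, adjusted p = 0.193 with an estimated correlation). Ifi44 rose 10.04-fold, Rtp4 2.81-fold, the signal transducer Stat2 2.53-fold and the restriction factor Bst2 2.17-fold.

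TGIF1 is a known corepressor of SMAD proteins, and the TGF-beta and SMAD list rose. Of 32 measured members 18 rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 1.42e-07, adjusted p = 0.171 with an estimated correlation). Junb rose 2.34-fold and the integrin Itgav 1.81-fold, next to Id2. Other lists also hold 7 of the 32 members, Junb and Id2 among them, so this rise is not separate from theirs. The receptor Tgfbr2 differed by 0.053 ± 0.11 on the log2 scale (adjusted p = 0.802), and by -0.055 with each array centred on its median. The retinoid list was not called (camera adjusted p = 0.0702). Of its 27 members 7 rose and 5 fell, the same when adjusted over the list alone, with Cd38 10.6-fold, the transglutaminase Tgm2 3.70-fold and the receptors Rara 2.61-fold and Rarg 1.79-fold higher. Array median centring called the list (adjusted p = 0.0374).

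Adhesion and homing genes rose more often than they fell, with 13 of 26 higher and 4 lower, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.000193, adjusted p = 0.171 with an estimated correlation). The integrin Itgb7 rose 9.65-fold, the chemokine receptor Ccr1 4.70-fold, the tetraspanin Cd9 3.90-fold and Jaml 2.08-fold. Dendritic cell and MHC class II genes were not called as a list (2 of 17 rose and 1 fell, the same when adjusted over the list alone, camera adjusted p = 0.124). In that list Cd74, the invariant chain, rose 3.10-fold and the integrin Itgax 1.69-fold, H2-DMa fell 1.93-fold, and Ccr7 did not pass (log2 0.30, adjusted p = 0.0703). It was called without pMIG-TGIF1 replicate 3 (0.38, adjusted p = 0.0283) and with array weights (0.33, adjusted p = 0.0373).

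Stress, death and sterol lists were not called, although quantile normalization called all 3 (adjusted p = 0.0217 for heat shock and integrated stress, 0.0364 for apoptosis and 0.0251 for cholesterol synthesis). Of 25 heat shock and integrated stress genes 9 rose and 5 fell, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.0702). Heme oxygenase Hmox1 rose 6.51-fold, Trib3 3.58-fold and the cystine transporter Slc7a11 3.16-fold, while Herpud1 fell 2.26-fold. The list was also called with array median centring (adjusted p = 0.0222) or without pMIG-TGIF1 replicate 3 (0.0306), and 3 members fell without pMIG replicate 1 or pMIG-TGIF1 replicate 1. Of 30 apoptosis genes 11 rose and 5 fell, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.160), with Casp6 2.40-fold and Bmf 1.93-fold higher and Bid 1.75-fold and Cycs 1.52-fold lower. Without pMIG replicate 2, 7 apoptosis genes rose, and without pMIG replicate 3, 3 fell. Of 24 cholesterol synthesis genes 9 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.160). With array median centring 6 of them rose and 2 fell, and the list's median log2 fold change turned from 0.047 to -0.061. Hmgcs1 rose 1.99-fold, Sqle 1.40-fold, Hsd17b7 1.38-fold and Nsdhl 1.37-fold. Without pMIG-TGIF1 replicate 1 the retinoid list (adjusted p = 0.0465) and the cholesterol list (0.0394) were called.

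Some markers of other lineages rose, up to 6 of 12 in the eosinophil list. With array median centring or quantile normalization, 1 gene also fell in each of the megakaryocyte and the T and NK cell lists. In the megakaryocyte list 6 of 16 rose and 0 fell, the same when adjusted over the list alone, with Treml1 2.00-fold higher beside Ppbp, Thbs1 and Pf4. Its mean log2 fold change was 1.00 and its median 0.11, or 0.18 without pMIG-TGIF1 replicate 1, 0.066 without replicate 3 of that group and 0.0049 with array median centring (camera adjusted p = 0.00154, adjusted p = 0.171 with an estimated correlation). In the eosinophil list 6 of 12 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.222 with an estimated correlation). The ribonuclease paralogs Ear2 (3.64-fold), Ear10 (3.21-fold, and 1.69-fold in a second, dimmer probe set) and Ear1 (2.92-fold), whose near-identical sequences were not separated here, rose with the lectin Siglecf (1.91-fold). Among T and NK cell genes 5 of 20 rose and 0 fell, the same when adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.191 with an estimated correlation), with Il7r 2.10-fold, Cd28 and Cd3d 1.63-fold and Cd5 1.46-fold higher. The median log2 fold change of this list was 0.17, or 0.063 with array median centring. Only 2 of its 20 genes, and 2 of the 20 stroma and endothelium genes, lay above the median of all transcript clusters in pMIG. Among stroma and endothelium genes 4 of 20 rose and 0 fell, the same when adjusted over the list alone. These were fibronectin Fn1 (7.22-fold), the actin Acta2 (2.16-fold), Postn (1.64-fold) and Tie1 (1.27-fold), with camera adjusted p = 0.0259 and adjusted p = 0.242 with an estimated correlation. That call was lost without pMIG replicate 3 (adjusted p = 0.0569), with the dimmest 30% of probe sets left out (0.0943) and with quantile normalization (0.115), and the list median of 0.089 was 0.14 without pMIG replicate 1 and 0.053 without pMIG replicate 3, and turned to -0.019 with each array centred on its median. Tie1 lost its call without pMIG replicate 2 (adjusted p = 0.0576) or 3 (0.0582), with array median centring (0.0737) and with quantile normalization (0.0641).

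The remaining lineage lists were not called. Of 21 erythroid genes 4 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.124). In pMIG 0 of these 21 lay above the median of all transcript clusters. Without any array other than pMIG-TGIF1 replicate 2 the number rising was 2, or 1 without pMIG replicate 3, and it was 2 with array median centring or quantile normalization. The 4 were the globin genes Hbb-bt (1.46-fold), Hbb-b2 (1.36-fold), Hba-a1 (1.30-fold) and Hba-a2 (1.24-fold), near-identical pairs that were not separated here. Of 19 mast cell and basophil genes Mitf rose 1.26-fold and Ms4a2 fell, so 1 and 1 were called, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.828). Mitf lost its call with array median centring (log2 0.22, adjusted p = 0.104), with the replicate block (adjusted p = 0.0577) and without any pMIG array or pMIG-TGIF1 replicate 3. Without pMIG replicate 1 or pMIG-TGIF1 replicate 1, and with array median centring or quantile normalization, there were 2 falls. Mcpt8 (log2 -0.47) and Mcpt1 (0.23) did not pass. Mcpt8 was called lower without pMIG replicate 1 (-0.59, adjusted p = 0.0424) or pMIG-TGIF1 replicate 1 (-0.59, adjusted p = 0.0316), with array median centring (adjusted p = 0.0266), with quantile normalization (0.0323) and with the dimmest 50% left out (0.0469). Of 18 B cell genes 3 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.188). Blnk rose 3.15-fold, Il7r 2.10-fold and Cd22 1.89-fold, and Pou2af1 fell 1.22-fold, a call lost on leaving out any single array, with the replicate block, with the intensity trend and robust prior and without moderation (adjusted p = 0.0513 to adjusted p = 0.161).

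**Figure D3:**
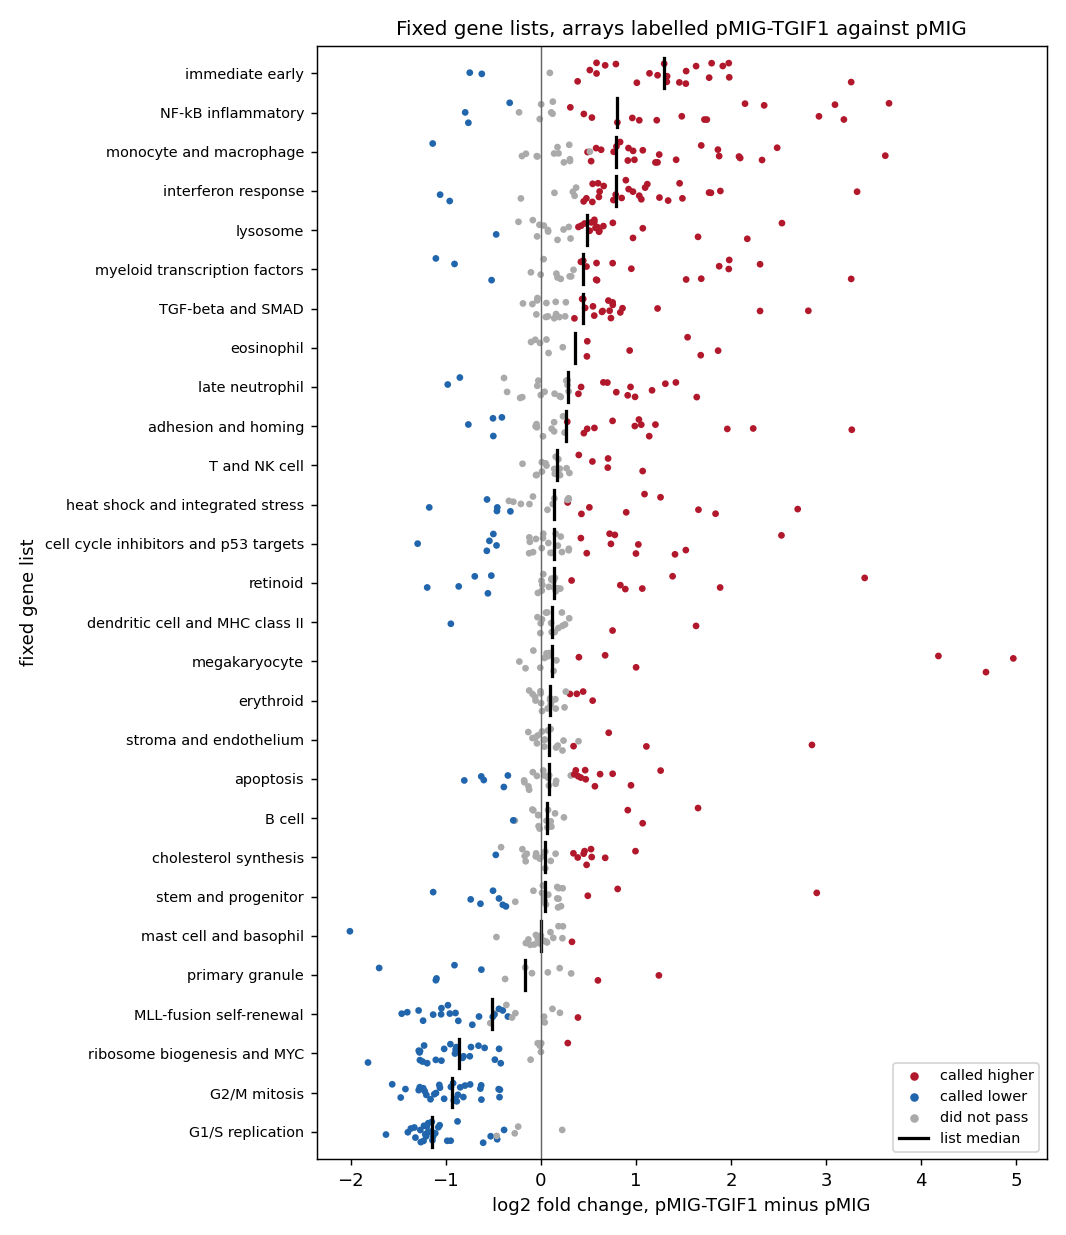
Log2 fold change between the arrays labelled pMIG-TGIF1 and the pMIG arrays (x axis) of each measured gene in the 28 fixed lists (y axis, sorted by median). Red and blue points were called higher and lower, grey points did not pass, and black bars are list medians. Medians ran from -1.14 for G1/S replication to 1.30 for immediate early genes.

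Of the 28 lists, 14 were called higher and 4 lower with the preset correlation, and 0 in either direction with an estimated correlation. At an unadjusted p under 0.05 the estimated correlation left 6 higher and 2 lower, and fry called 19 and 5. Lists that fry called higher and camera did not were heat shock and integrated stress (fry adjusted p = 0.000951), retinoid (0.00413) and B cell (0.0267). Apoptosis (0.0269) and dendritic cell and MHC class II (0.0283) were so too, and primary granule was called lower by fry alone (0.0188).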

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

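The tests of an exchange of arrays, of vector probes, of megakaryocytes, of tissue macrophages and of array medians were chosen only after the result was seen, and the count of splits for lists was taken over the larger direction of each split after a first version had been seen.

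Probe sets without a gene symbol lay outside the comparison, and 138 of these 3730 were called with at least a 1.5-fold change, 71 higher and 67 lower. They are a signal outside the main comparison, used only in the alternative that tests all probe sets. Their share of such calls, 3.70%, lay below the 12.3% of the named transcript clusters, and of calls of any size they held 8.18% against 24.7%. What they read is unknown here.

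The Tgif1 probe set was lower in the arrays labelled pMIG-TGIF1 (log2 -0.58). An exchange of 1 or 2 arrays between the groups is argued against by the array correlations, since 0 of the 6 arrays correlated better with an array of the other group than with one of their own. An exchange of both whole groups would leave those correlations as they are and stays open. A vector transcript outside the probes, with less of the cells' own Tgif1 transcript, may also give this reading, and the value of -0.58 does not decide it, because no probe sequence or vector probe was at hand. A biological effect of the TGIF1 vector on the cells' own gene is likewise untested.

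Ppbp, Pf4 and Thbs1 rose by at least 4.18 on the log2 scale. Megakaryocytes or platelets among the sorted cells could bring these transcripts, and would bring others of that lineage too. The other 13 measured megakaryocyte genes had a median log2 fold change of 0.075 with an SD of 0.34. That median lay under the bound of 2.09, which was set for this explanation after the result was seen. Of these 13 genes 3 were called higher, and the highest, Treml1, reached 1.00. The 13 were not chosen for abundance. Only 5 of the 16 measured list genes lay above the median of all transcript clusters in pMIG, and RMA compresses the folds of dim probe sets. An admixture that shows only in the most abundant transcripts is therefore not excluded. An effect of the vector on these 3 genes within the cells stays open as the design's own explanation, untested.

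The monocyte and macrophage list rose, with 24 of 37 genes called. The difference in array medians is argued against as the whole cause, because 23 genes were still called higher with each array centred on its median. Tissue-type macrophages carried along in the sort may add to the rise, although the GFP gate would remove cells that were not transduced. The median log2 fold change of 8 tissue macrophage genes was 0.25, with quartiles of -0.077 and 1.12, and it leaves that open. Of the 8, Mertk (2.49), Mrc1 (2.08) and C1qc (0.80, adjusted p = 0.0326) rose and Cx3cr1 fell (-1.14), while C1qa (-0.036), C1qb (0.31), Apoe (-0.20) and Csf1r (0.19) did not pass. Since these genes went both ways, a change within the leukemic cells cannot be told apart here from such an admixture. An effect of the vector on the cells is the design's own explanation and stays open, untested.

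The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The labelled split called 6200 transcript clusters, 2892 higher and 3308 lower, and 3092 with at least a 1.5-fold change, and it was the 1 split of 10 with counts as large. In each of the 9 others limma called 0. At an unadjusted p under 0.05 it gave 8552 against at most 812 in the others. The labelled split called 14 lists higher and 4 lower with camera at the preset correlation. Another split reached 11 lists in one direction while calling 0 transcript clusters. Each of the 9 others still sets 2 arrays of one label beside 1 of the other on each side, so part of the labelled difference stays in them, which adds to their list calls and to the spread that their gene calls are held to. They are no measure of what unchanged cells would give. A split has no direction of its own. Taking the larger direction of each other split, 1 of 10 splits reached the 14 lists called higher and 9 of 10 reached the 4 called lower. Setting the smaller direction of each split against the 4, 4 of 10 reached it.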

How the results depend on the processing

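All alternatives were fixed before the data were examined. Of the 36 genes that were steepest or chosen in advance 30 were called, and 25 of these were called under each of the 17 alternative gene fits that tested them; Kit, Cd34, Hoxa9, Kbtbd8 and Cdkn1a lost the call under at least 1. Of the 99 further list members that the naming rule took 96 were called, and 86 of these under each alternative gene fit that tested them. Hba-a1, Hba-a2, Hbb-bt, Mitf, Pou2af1 and Tie1 lost the call without at least 1 array, and Hbb-b2, Cd28, Hmgcs1 and Ms4a3 only without moderation. Members named as examples outside the rule were not counted here. The Tgif1 fall kept its direction and its call in all 17 alternative gene fits. Among these 17, the fit of the other deposited table used the same intensities and could not differ from the main fit. Without moderation 3401 transcript clusters were called, 1754 higher and 1647 lower, since each variance then rests on its own 6 values. With an estimated correlation 0 lists were called higher and 0 lower. The estimates reached 0.80 for G1/S replication, 0.61 for ribosome biogenesis and 0.49 for G2/M mitosis, far over the preset 0.01. The T and NK cell list (0.021) and the megakaryocyte list (0.035) lost the call at low estimates too. The estimates lay under the preset for heat shock and integrated stress (-0.0043), primary granule (-0.029) and mast cell and basophil genes (-0.0013). With the estimate the unadjusted camera p still went from 0.0477 to 0.0922 and from 0.104 to 0.160 for the first lists. For mast cell and basophil genes it stayed at 0.83. These values argue against high correlations as the whole cause of the larger p-values. What else adds to it was not tested. Leaving out 1 array each gave 4860 to 5911 calls.

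Some uncalled results turned direction, and the cause was not tested. Tgfbr2 was -0.055 with array median centring. Leaving out single arrays gave ranges of -0.14 to 0.048 for Tgif2, -0.035 to 0.15 for Tgfbr2, 0.015 to 0.11 for the median of the stem and progenitor list and -0.015 to 0.047 for that of the mast cell and basophil list. The direction that the list test gave turned for the former list without pMIG-TGIF1 replicate 2 (median 0.11) and with fry (median 0.040), and for the latter without pMIG-TGIF1 replicate 3 and without moderation (median 0.000696). The former list's median was -0.068 with array median centring and -0.024 with quantile normalization.

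No pairing by replicate number showed. Deviations from the group means correlated at -0.19, -0.11 and -0.05 between same-numbered arrays, and at -0.067 to 0.18 between the others. With 3 arrays per group these few correlations cannot exclude a pairing. With the replicate block 5536 transcript clusters were called (2579 higher, 2957 lower), with 14 lists higher and 4 lower, and Kit lost its call (adjusted p = 0.0547). What signal over background limits is unknown without detection calls; leaving out the dimmest 50% changed the share of calls that were higher to 40.8%.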

Other observations

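All tests in this part were chosen only after the data had been seen, on gene families defined by symbol and on neighbouring genes.

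Translation genes outside the ribosome biogenesis list fell in part in the arrays labelled pMIG-TGIF1. Of 77 mitochondrial ribosomal protein genes 28 fell and 1 rose (median log2 -0.20), and of 20 aminoacyl-tRNA synthetase genes 11 fell and 0 rose, with Vars at -1.22 ± 0.13 (SE) and Yars at -1.04 ± 0.11. Camera gave adjusted p-values of 4.33e-07 and 0.000430, with adjusted p = 0.247 and adjusted p = 0.335 with an estimated correlation. Of 84 cytosolic ribosomal protein genes 2 fell and 1 rose (median -0.071, camera adjusted p = 0.0231, adjusted p = 0.487 with an estimated correlation). Of 39 proteasome genes 5 fell and 2 rose (camera adjusted p = 0.1004). Of 9 genes whose symbol is Mcm with a number, mostly replicative helicase subunits that the replication list holds too, 8 fell (median -1.11, camera adjusted p = 1.34e-06, adjusted p = 0.247 with an estimated correlation). Solute carriers went both ways, with 64 of 374 higher and 50 lower (adjusted p = 0.250).

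Among chemokine, lectin and Ms4a genes, which encode secreted and surface proteins, more rose than fell, while most chemokine and lectin genes did not pass. Of 36 chemokine ligand genes 13 rose and 1 (Cxcl10, -0.96 ± 0.20) fell (camera adjusted p = 6.13e-06, adjusted p = 0.0790 with an estimated correlation). Cxcl2 was at 3.09 ± 0.25, Cxcl3 at 2.31 ± 0.09 and Ccl7 at 2.29 ± 0.20 on the log2 scale. The chemokines Ppbp and Pf4 carry symbols of another form and were not among the 36. Some of the 36 also stand in fixed lists, such as Cxcl2 in the NF-kB list and Cxcl10 in the interferon list. Of 32 Clec lectin genes 12 rose and 1 fell, with Clec4d at 2.65 ± 0.14 and Clec10a at 2.00 ± 0.10 (camera adjusted p = 1.06e-05, adjusted p = 0.165 with an estimated correlation). Of 20 Ms4a genes 8 rose and 2 fell, with Ms4a8a at 2.53 ± 0.10 and the granulocyte progenitor gene Ms4a3 at -1.70 ± 0.29 (camera adjusted p = 0.00545, adjusted p = 0.247 with an estimated correlation).

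A hypothesis is that genes which rose at least 2-fold lie next to each other more often than chance gives. Among 19457 protein-coding genes placed along the chromosomes, 591 rose at least 2-fold and made 32 adjacent pairs whose symbols differ in their first 2 characters, against 19.3 expected from 10000 permutations within 10 bins of intensity (one-sided permutation p = 0.00420). The name rule and the bins were tightened after a first version had been seen. That version, with names unlike in 3 letters and permutation over all genes, gave 41 pairs against 15.3 (permutation p = 0.0001, the smallest that these permutations can give). The other 2 forms gave permutation p-values of 0.0001 and 0.000200. Without a name rule there were 71 pairs. Pairs include Osm and Lif, Bco2 and Il18, Id2 and Rnf144a, and Abca1 and Slc44a1. Ppbp, Pf4 and Cxcl3 are related chemokines that the rule let through, and the other pairs, Osm and Lif among them, were not checked for such relation. Shared local regulation, duplicated genes and probes that read a neighbour's transcript may each add pairs, so the 32 pairs do not say which applies. For the 359 genes at least 2-fold lower the same test gave 9 pairs against 7.60 (permutation p = 0.350) and leaves the question open. The first version had given 11 pairs (permutation p = 0.0267), so its call rested on the form of the test.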
